A study of Mus musculus with 2 samples.

How the data were processed

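The series holds 2 ribosome profiling libraries of mouse spinal cord, 1 from wild-type animals and 1 from animals heterozygous for Gars C201R. Per the labels' protocols, tissue of 3 animals of a genotype was lysed and the lysates were pooled, ribosome-bound fragments were produced with RNase I, size-selected and made into a cDNA library. Because animals were pooled before library construction, the tables hold no variation between animals. Bowtie 1.2.2, HTSeq 0.9.1 and the mouse genome build GRCm38 are named per the submitters' processing notes. Their settings, the annotation release, the strand setting, the treatment of ribosomal RNA reads and of fragment lengths, and the part of the gene that was counted are not given in the sources used here. Genes that share reads with near-identical copies, overlapping genes and antisense genes could therefore not be told from genes with reads of their own.

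Per the file headers, the authors deposited a read count and an RPKM value for each gene. The counts are whole numbers and were used as deposited. The RPKM values were deposited by the authors as reads scaled to gene length and to the total reads of the library, and were used to find how the tables were made. Dividing reads by RPKM gave whole-number gene lengths in every row, within 1e-06 nt, for a single total of 7790126 reads in the wild-type and 3520348 reads in the heterozygous library. These totals exceed the listed reads by 18671 and 6332 reads. The lengths recovered from both libraries were identical, with a median of 3092 nt over the genes, and 33.7% were multiples of 3, as for lengths that are not those of coding sequences alone. The lowest deposited RPKM was 0.183 in the wild-type and 0.501 in the heterozygous library, and no row lacked reads in either library. Genes below those levels are not in the comparisons. No column of another series was present.

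The 12530 genes were analysed apart from the 18 ERCC spike-ins, which took no part in the scaling. Library sizes were scaled with TMM in edgeR 4.0.16 under R 4.3.3. The log2 ratio of the heterozygous over the wild-type library was computed with a prior count of 0.5 per library, scaled to library size. Its interval is the exact conditional binomial (Clopper-Pearson) interval at 95%. Poisson intervals of single counts are exact, and shares have Wilson intervals. Reads may not be independent molecules, which the intervals do not allow for. All intervals cover counting error only and leave out variation between animals, pools and libraries. A gene was counted as higher or lower when it had 100 or more reads in both libraries together, its interval excluded equal levels and its ratio was at least 1.5-fold. No model of genotype was fitted and no p-value between genotypes was computed, because 1 library per genotype leaves no residual degrees of freedom. A straight line of the robust variance of the log2 ratio on the counting variance was fitted over 10 groups of genes ordered by reads, to describe the spread. Folds of the spike-ins were computed without the prior count, except in the plot of ratios by reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

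The calling rule was tested on simulated data, drawn at the real mean levels and library sizes with counting error only, with 9723 genes past the minimum. It recovered 100% of the 50 genes raised 2-fold, 100% of the 50 raised 4-fold, 94% of the 50 lowered to a ratio of 0.5 and 90% of the 50 lowered to a ratio of 0.25. It called 0.472% of the unchanged genes, and 95.5% of the intervals held the simulated ratio. That share is close to 95% by construction, as the draws held counting error only. The 2 libraries varied by more than counting error, so these rates do not describe the rule on the real data.

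The groups, the calling rule, the gene lists and most alternatives were set before the data were examined. Genes were to be named by the bound of the counting interval nearest to equal levels, with Gars, fixed stress and cell type genes and the members of 40 fixed lists. The files give Ensembl identifiers only, and 0 of them matched a symbol in the reference table of 49997 genes used here, which holds no Ensembl identifiers. Symbols were not inferred from identifiers, so the rule was applied to identifiers, of which the first 2 on each side are printed, and the lists, Gars and the relation to glycine codon content were not analysed here. Pseudogenes and predicted genes that the rule was to leave out were likewise not recognised. The alternatives tried for the counts of genes were total-count, DESeq2 1.42.0 and upper-quartile scaling, leaving out genes above 1% of a library, a minimum of 20 or 500 reads or none, a 99% interval, a 2-fold limit and thinning of the wild-type library to the depth of the other. Scaling to the spike-ins, scaling to the totals of the RPKM values and a common RPKM minimum were added after seeing the data.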

Results

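Ribosome-protected fragments were sequenced from mouse spinal cord tissue of wild-type animals and of animals heterozygous for the C201R missense allele of Gars. Gars encodes glycyl-tRNA synthetase, the enzyme that attaches glycine to its tRNAs. There was 1 library per genotype, and each library was made from the pooled lysates of 3 animals. The series as designed asked how ribosomes are distributed over glycine codons in mutant tissue. The tables analysed here hold 1 read total per gene and no position within a gene, so occupancy at codons was not analysed here. The comparison that these totals allow is the level of each gene in the heterozygous library against the wild-type library. Level here means the scaled number of reads counted for a gene. Whether each read came from a ribosome-protected fragment could not be checked from totals. The series holds no RNA library, so mRNA amount, translation and the speed of ribosomes could not be told apart.

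Each table listed the same 12530 mouse genes and 18 ERCC spike-ins, synthetic RNAs of a kind used as external controls. The listed reads summed to 7771455 in the wild-type library and to 3514016 in the heterozygous library, a 2.21-fold difference in depth. The median gene had 206 reads in the wild-type library and 96 reads in the heterozygous library. The single most abundant gene took 1.01% of the gene reads in the wild-type library and 1.07% in the heterozygous library. The 100 most abundant genes together took 23.5% and 22.8%, and 89 of the 100 were shared between the libraries. Each listed gene had at least 1 read in both libraries, so genes seen in 1 genotype alone were not among the values compared. Genes are given by Ensembl identifier, because neither the tables nor the reference table used here pairs these identifiers with symbols. For the same reason the level of Gars itself and the 40 gene lists fixed beforehand, among them targets of the integrated stress response and markers of spinal cord cell types, are not reported here.

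The profiles of the 2 libraries were similar in rank. Among the 9726 genes with 100 or more reads in both libraries together, 7839 genes (80.6%) differed by less than 1.5-fold after TMM scaling. The counting interval excluded equal levels for 5050 genes (51.9%), most of them by less than that fold. The read numbers of these genes had a Spearman correlation of 0.944 between the libraries, and their log2 CPM (counts scaled to library size) a Pearson correlation of 0.952. Both correlations are across genes, which are not independent replicates. The level was at least 1.5-fold higher in the heterozygous library, with a counting interval that excluded equal levels, for 792 genes (8.14%). It was lower by the same rule for 1087 genes (11.2%). Differences of 4-fold or more were few, with 7 genes higher and 18 genes lower. Only 5 genes were higher and 4 genes lower by 8-fold or more. The lowest listed RPKM was 0.501 in the heterozygous and 0.183 in the wild-type library. No gene under 0.501 in the heterozygous library was listed, so large decreases may be undercounted. This limit weighs more on long genes, whose RPKM is lower for the same reads. Large increases may be undercounted too, because the minimum of 100 reads rests more on the deeper wild-type library. ENSMUSG00000002324, for example, had 17 wild-type and 79 heterozygous reads and a log2 ratio of 3.27, but fell under the minimum.

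With 1 library per genotype no difference has a replicate check and no p-value between genotypes was computed. The intervals cover counting error only and compare these 2 libraries, not the genotypes. Which direction held more genes depended on the scaling and on the read minimum: scaling to total gene reads instead of TMM gave 952 genes higher and 919 lower, and TMM with no read minimum gave 1379 higher and 1353 lower, against 158 and 348 with a minimum of 500 reads. A lower read minimum admits genes of low RPKM, none of which was listed under 0.501 in the heterozygous library. Those genes leaned towards that library, as described below. A common RPKM minimum was tried only with 100 reads.

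**Figure D1:**
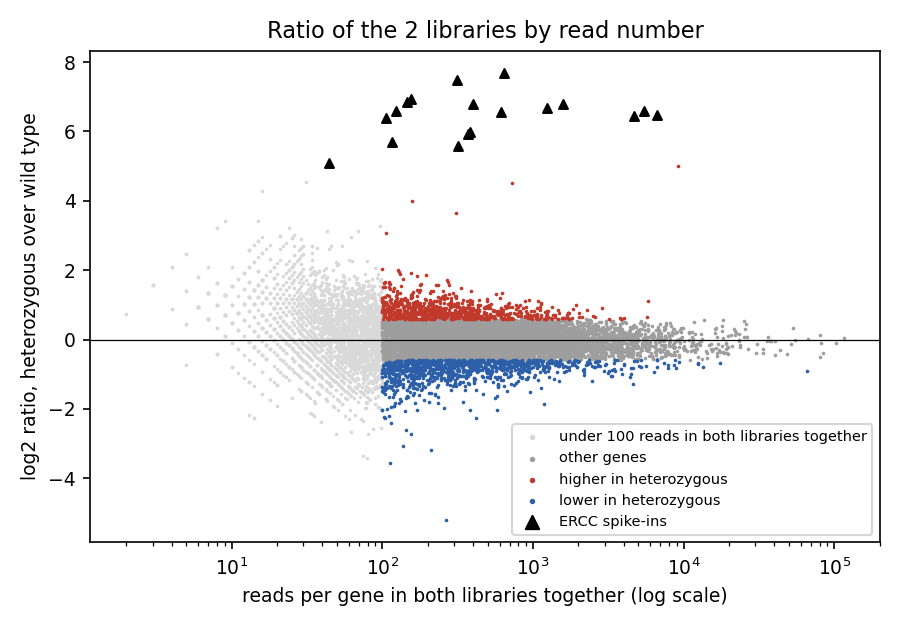
Log2 ratio of the heterozygous over the wild-type library (vertical axis, TMM-scaled) against the reads of each gene in both libraries together (horizontal axis, log scale), with 1 point per gene and 1 black triangle per ERCC spike-in. The 792 genes called higher and the 1087 called lower lie on both sides of a dense band around 0, and all 18 spike-ins lie above every gene.

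The gene that stood furthest above equal levels was ENSMUSG00000035202, with a length (as used for the RPKM values) of 3894 nt. It had 568 reads (95% Poisson interval 522 to 617) in the wild-type library and 8555 reads (8375 to 8738) in the heterozygous library. Its log2 ratio was 5.01 (95% counting interval 4.89 to 5.14), and its share of the gene reads was 0.00731% in the wild-type and 0.245% in the heterozygous library. ENSMUSG00000000093, with a length of 3626 nt, came next. It had 62 reads (47.5 to 79.5) in the wild-type library and 663 reads (613 to 715) in the heterozygous library, a log2 ratio of 4.50 (4.14 to 4.92). The treatment of ribosomal RNA reads and the part of the gene that was counted are not given. For the genes named here and below, reads of their own could therefore not be told from reads of near-identical sequences. The intervals do not cover this.

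Among the listed genes, the one furthest below equal levels was ENSMUSG00000057841, which is 517 nt long. It had 262 reads (231 to 296) in the wild-type library and 3 reads (0.619 to 8.77) in the heterozygous library, a log2 ratio of -5.21 (-7.63 to -3.78). ENSMUSG00000028832, with a length of 1060 nt, had 199 reads (172 to 229) in the wild-type library and 10 reads (4.80 to 18.4) in the heterozygous library. Its log2 ratio was -3.17 (-4.30 to -2.30). The direction of these 4 genes was the same under each scaling that was based on gene reads. Those scalings differ too little to turn ratios of this size, with ENSMUSG00000035202 between 5.01 and 5.07, so this is no check of direction. Directions are relative to the gene reads, since a scaling to the spike-ins would shift every gene by 1 common factor.

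Weakly covered genes differed more between the libraries than well covered genes did, and by more than counting error. Genes were split into 10 equal groups by reads. In the group with the fewest reads, 100 to 145 in both libraries together, the log2 ratio had a robust SD of 0.68 across 995 genes, against 0.28 from counting error alone, and 37.6% of the genes were called higher or lower. In the group with the most reads, from 2152 upwards, the robust SD was 0.32 across 973 genes, against 0.05 from counting error, and 7.71% were called. Direction varied little with gene length. In 10 groups by length, the median log2 ratio was 0.0011 in the shortest genes and -0.10 in the longest, and the Spearman correlation of ratio and length across genes was -0.045. The spread did vary with length. The robust SD was 0.55 in the shortest genes, with 26.8% called, and 0.36 in the longest, with 13.2% called. The shortest genes also had fewer reads, with a median of 373 against 621. Beyond counting error the SD was still 0.52 in the shortest and 0.34 in the longest genes. The counting error of fewer reads was therefore not the whole difference.

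**Figure D2:**
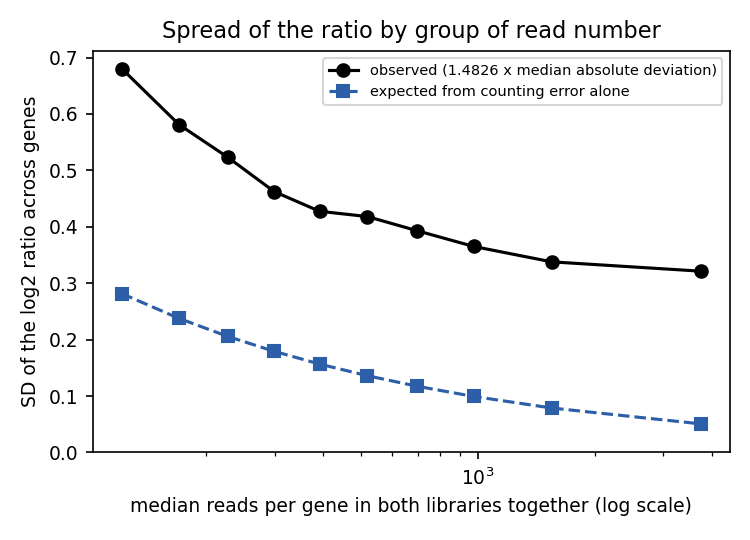
Spread of the log2 ratio across genes (vertical axis, SD in log2 units) in 10 equal groups of genes ordered by reads (horizontal axis, median reads in both libraries together, log scale). The observed robust SD (circles) fell from 0.68 to 0.32 and stayed above the SD that counting error alone gives (squares), which fell from 0.28 to 0.05.

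As a group, the ERCC spike-ins were higher in the heterozygous library by more than any gene was. The labels do not state when or whether spike-ins were added, so equal amounts in both libraries cannot be assumed. They held 520 reads, or 0.00669% of the listed reads (95% Wilson interval 0.00614% to 0.00729%), in the wild-type library and 22857 reads, or 0.650% (0.642% to 0.659%), in the heterozygous library. Relative to the gene reads, without a prior count, this was a 94.3-fold difference (95% counting interval 86.4 to 103). Every one of the 18 spike-ins was higher, by 45.0-fold at the lowest, ERCC-00044 with 2 and 42 reads (interval 11.7 to 384), and by 228-fold at the highest, ERCC-00004 with 6 and 639 reads (104 to 625). The 3 spike-ins with 100 or more wild-type reads had close ratios of heterozygous to wild-type reads. These were 41.2 (34.1 to 50.1) for ERCC-00002, 45.4 (37.8 to 54.9) for ERCC-00096 and 41.6 (35.4 to 49.0) for ERCC-00130. The composition of the spike-in reads did not differ detectably between the libraries (chi-square 21.7 with 17 degrees of freedom, p = 0.193 in a permutation test with 100000 draws). Of the 18 spike-ins, 9 had fewer than 10 wild-type reads, and their ratios have wide intervals.

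**Figure D3:**
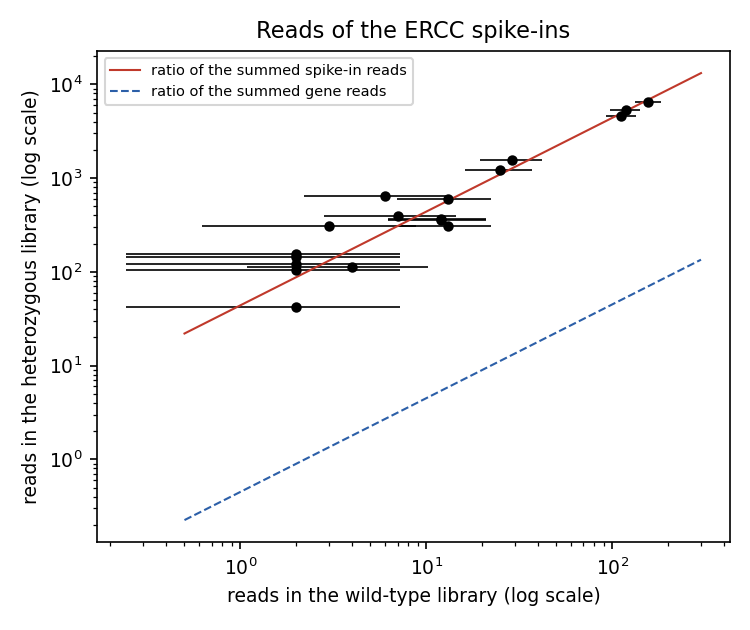
Reads of the 18 ERCC spike-ins in the heterozygous library (vertical axis) against the wild-type library (horizontal axis), both on log scales, with 95% Poisson intervals on the wild-type reads. The points follow the ratio of the summed spike-in reads (solid line, 44.0) and lie far above the ratio of the summed gene reads (dashed line).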

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

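The tests of the spike-in reads were chosen after those values had been seen, and so was the test of independent reads. The test of the row selection was also chosen after the files had been seen, though before its own result. The test of counting error was set before its result was seen. The ERCC spike-ins, a signal outside the mouse genes that the main comparisons rest on, made up 0.650% of the heterozygous library and 0.00669% of the wild-type library. A difference in sequencing depth is argued against, since the difference was 94.3-fold after scaling to the gene reads and the heterozygous library was the shallower one. Mixtures that differ widely in the 3 spike-ins with 100 or more wild-type reads are argued against. Their ratios of heterozygous to wild-type reads lay between 41.2 and 45.4. For the other spike-ins different mixtures stay open, because 9 of the 18 had fewer than 10 wild-type reads. The permutation p of 0.193 for equal composition does not show equality. The same composition would also follow from 1 mixture added in unequal amounts, or from reads of a spiked library that were assigned to the wild-type library, and the tables hold no value that separates these. Without a prior count on either side, 0 of the 12530 genes were higher by the lowest spike-in ratio of 45.0-fold or more, and the highest gene was at 32.3-fold.

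Counting error alone is argued against as the cause of the second pattern, the 1879 genes called higher or lower, since unchanged libraries drawn with counting error gave a median of 55 and at most 74 such genes in 100 draws. Across the 10 groups of genes ordered by reads, the variance of the log2 ratio rose by 4.60 (SE 0.147) for each unit of counting variance, on top of an SD of 0.29. A candidate explanation is that reads are not independent molecules, for example through amplification, which would make each interval too narrow. The spike-ins did not show such an excess, with a chi-square per degree of freedom of 1.28 (95% interval 0.719 to 2.87), but this leaves it open, because wild-type spike-in reads that came from the other library would not carry the duplication of the wild-type library. Variation between libraries unrelated to genotype, with an SD of 0.32 beyond counting error in the most covered genes, cannot be told apart from a difference between the genotypes, because there is 1 library of each.

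The third pattern concerns weakly covered genes, where the 700 genes with a mean RPKM under 1 had a median log2 ratio of 0.38, against -0.0098 for the other 11830 genes. The row selection of the deposited tables is a candidate explanation, as the lowest listed RPKM was 0.501 in the heterozygous and 0.183 in the wild-type library. With 0.501 as the minimum in both libraries, 437 of the 700 genes were left and their median was -0.0061. That minimum by itself removes genes that were low in the wild-type library, so a real difference among the weakest genes is not excluded. Genes with a mean RPKM between 1 and 2 had a median of 0.078.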

How the results depend on the processing

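Total-count, DESeq2 and upper-quartile scaling, leaving out the gene above 1% of a library, a 99% interval, thinning the wild-type library and, chosen after seeing the data, the totals of the deposited RPKM values and a common RPKM minimum gave 653 to 952 genes higher and 848 to 1091 genes lower. A minimum of 20 reads gave 1321 higher and 1353 lower among 12160 tested genes. No minimum gave 1379 and 1353 among 12530, and a minimum of 500 reads gave 158 and 348 among 4480. A 2-fold limit left 166 higher and 267 lower by its construction. Total-count scaling moved every ratio up by 1 common amount, so all 792 genes called higher stayed called by construction. Of the 1087 called lower, 919 stayed called. Thinning left 8457 tested genes, and 542 of the 792 and 718 of the 1087 were still called. The thinned reads are part of the same library, so this is no replicate check. Scaling to the spike-ins, chosen after seeing the data, moved the median log2 ratio of the tested genes from -0.034 to -6.58 and gave 0 genes higher and 9726 lower. It turned ENSMUSG00000035202 to -1.55 and ENSMUSG00000000093 to -2.04, because it shifts every gene by 1 common factor larger than any gene's own ratio, so it says nothing about single genes. Under the 12 other alternatives these 2 genes stayed between 4.50 and 5.07. Limits on reads, RPKM, fold or interval cannot change a ratio, so only the scalings and the thinning could have moved them. The spike-in difference itself lay between 94.1-fold and 97.8-fold under 5 other scalings. The alternatives planned for Gars, for the gene lists and for glycine codon content were not run, because no identifier had a symbol or a coding sequence here. Mitochondrially encoded genes were not recognised, so only the gene above 1% of a library was left out. No replicate could be left out. Depth limits the genes with 100 to 145 reads to a counting SD of 0.28 on the log2 scale.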
